A study of Mus musculus with 8 samples.

How the data were processed

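The study measured messenger RNA in single CD45-positive cells from tumours of KPC.2, a mouse pancreatic cancer line, grown under the skin of C57BL/6 mice after injection of 2000000 cells. Animals of the treated group received 100 µg of an antibody against PD-1 and 100 µg of an antibody against CTLA-4 on days 6 and 9. Tumours of both groups were collected on day 12. Immune cells were enriched on a density gradient (Lympholyte-M) and then by magnetic selection for CD45, so cell shares describe cells that passed both steps and the droplet capture, not the composition of the tumour. Libraries were made with 10x Genomics 3' chemistry, 1 per tumour, with 4 untreated and 4 treated tumours. The labels name no control antibody for the untreated animals.

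The deposited files give raw UMI counts per gene and cell barcode, for barcodes that the authors' pipeline had already called as cells. The values are whole numbers with no normalization. The submitters' processing notes name Cell Ranger 3.0.0 and the mouse build mm10. The files pair 32285 gene identifiers with symbols, and 32158 of these identifiers were found in GENCODE vM21, from which gene positions on mm10 were taken. The 38 symbols that belong to more than 1 identifier were kept apart by identifier.

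The 8 libraries held 39632 barcodes and 131370421 UMIs, with 13625824 to 16616788 UMIs per untreated library and 15493612 to 22061451 per treated library. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 34290 cells. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold marked between 0 and 5 cells per library, so the highest-scoring cells were removed instead, up to the rate that loading predicts (0.8% per 1000 cells). This removed 1236 cells, and 33054 cells with 115782203 UMIs were retained. Clusters with marker genes of 2 lineages remained after this step and were left unnamed. This threshold for doublets was changed after the automatic one had been seen.

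Counts were scaled to a common total per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours with shared-neighbour weights and the Leiden algorithm (igraph 0.11.9) at resolution 1. Lymphoid and myeloid cells were clustered again separately by the same steps. Genes of the proliferation, interferon and MHC lists, immunoglobulin and T cell receptor segments, and mitochondrial, ribosomal and haemoglobin genes were kept out of the variable genes. No batch correction was applied. Clusters were named from marker lists of 21 cell types that were fixed before the data were examined. The numerical naming rule was chosen after the clusters were seen, from marker genes only and without reference to the treatment: a score of at least 0.3, at least 3 markers detected in at least 20% of cells, no low UMI count without a marker among the 10 leading genes, no other lineage at 0.45 of the best score or above, no other list with more markers among those leading genes, and for T cell subsets a coreceptor seen in at least 2 times as many cells as the other coreceptor. Another definition of leading genes, with a larger pseudocount of 0.5, was also looked at and is among the alternatives. Names carry the ending "-like", since they rest on transcripts alone. Of the retained cells, 6282 in 17 clusters stayed unnamed, and T cell clusters without a clear subset form a class of their own.

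Shares were computed per library and compared between groups with an exact two-sided permutation test over all 70 assignments of the labels, for which the smallest possible p is 0.0286. The threshold is this p under 0.05, with the Benjamini-Hochberg adjusted value over the family beside it. For expression, UMIs were summed per library and class. Classes with at least 20 cells in at least 3 libraries per group were fitted with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test), separately per class, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. This gave 11 classes, and the summed retained cells of each library were fitted as a further comparison. The standard error beside a log2 fold change is the fold change divided by the square root of its F statistic. Values per library are the CPM of edgeR within a class, given as mean ± SD.

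Gene lists for responses were fixed before the data were examined and overlap in part. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, for lists with at least 5 measured genes, which gave 235 tests. Camera asks whether a list moved more than the other genes. An estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without reference to other genes, were run beside it. Differences of a list between 2 classes were tested on each animal's difference in mean log2 CPM with the exact permutation test.

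Named genes follow a rule fixed before the data were examined. In the 3 classes with the most called genes it takes the 10 higher and the 10 lower called genes with the largest fold changes, and elsewhere 3 and 3. A gene qualifies with a mean log2 CPM of at least 4 and with the treated libraries all on the same side of the untreated libraries. Antigen receptor segments, mitochondrial and ribosomal genes and markers of other classes are left out of this ranking. The rule adds members of each called list by smallest p (2 to 4 in the plan, of which 2 were taken), and a few genes such as Pdcd1, Ctla4, Ifng, Gzmb and Mki67 in T cells and Nos2, Arg1, Cxcl9, Cd274 and Il1b in macrophages and monocytes whatever their result.

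Power was tested on simulated data. Counts were drawn with the library sizes and dispersions of a class, and a random set of genes and the list for MHC class I presentation were given known changes between the groups. Of genes with a 2-fold change, edgeR recovered 74.7% in the neutrophil-like class (6069 genes tested), 80.0% in the CD8 T-like class (6259), 54.0% in the macrophage-like class (10153) and 38.0% in whole libraries (12895). For a 1.5-fold change these shares were 34.7%, 26.3%, 8.0% and 6.0%. Between 5.6% and 8.7% of the calls were false with edgeR. With DESeq2 1.42.0 these were 6.5% (neutrophil-like), 5.8% (CD8 T-like), 14.3% (macrophage-like) and 21.9% (whole libraries). In the same order DESeq2 recovered 71.7%, 68.0%, 64.0% and 66.0% of genes with a 2-fold change. For a 1.5-fold change it recovered 35.8%, 20.2%, 20.0% and 30.0%.

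The alternatives tried were each replicate left out in turn, doublets kept, a stricter cell filter (at least 500 genes and at most 5% mitochondrial UMIs), Leiden resolution 2, other size factors, DESeq2, no gene filter, at least 50 cells, shares without non-immune or without unnamed clusters, edgeR on cell numbers, T cell subsets from a gate on single cells, classes without their cycling clusters, and the replicate number as a block. The gate within T cell clusters, the gate for expression, cycling clusters left out, unnamed clusters left out, list differences over genes tested in both classes and the other naming rules were added after the data were seen. The plan stated that 3 against 4 libraries cannot reach p = 0.05 in an exact test. This was wrong, since 35 assignments give a smallest two-sided p of 0.0286, and the tests with a replicate left out were read accordingly. The labels do not say that replicate numbers pair the libraries, and a check of correlations gave little sign of it. The block therefore stands among the alternatives only. No pair of libraries was a duplicate of another. Other splits of the libraries into 4 and 4 were refitted for each count of genes. Python 3.11.15 and R 4.3.3 were used. A list of sex-linked genes had too few measured members and was not tested. Results of 1 gene, which was analysed and is included in the counts, are not reported here.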

Results

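Antibodies against PD-1 and CTLA-4 were compared with no treatment in subcutaneous KPC.2 pancreatic tumours of mice, with 4 tumours per group, by single-cell RNA sequencing of CD45-selected cells. After filtering, 33054 cells remained, from 3318 to 4010 per untreated tumour and from 3351 to 6032 per treated tumour. The median UMI count per retained cell lay between 2277.5 and 2485.5 in untreated libraries and between 2786 and 2902 in treated libraries 1 to 3, but at 1377 in treated 4. That library also had 752 median genes per cell against 1213 to 1273 in the other treated libraries. The share of barcodes passing the filter was 83.4 ± 2.76% in untreated and 88.9 ± 1.61% in treated libraries (exact p = 0.0286, adjusted p = 0.0857), and the median mitochondrial share was 4.19 ± 0.043% and 3.80 ± 0.21% (exact p = 0.0286). Of the cells, 6282 in 17 clusters stayed unnamed (17.4 ± 2.32% of untreated and 18.5 ± 12.5% of treated cells), and 2221 of them came from the 6032 cells of treated 4.

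CD8 T-like cells formed a larger part of the T cells in treated tumours. They made up 17.1 ± 3.95% of T cells in untreated tumours (11.9 to 21.5%) and 45.1 ± 5.0% in treated tumours (39.3 to 49.6%), a difference of 28.1 points with all 4 treated tumours above all 4 untreated ones (exact p = 0.0286, adjusted p = 0.1). The log2 ratio of CD8 T-like to regulatory T-like cells rose from 0.04 ± 0.40 to 1.65 ± 0.27 (exact p = 0.0286, adjusted p = 0.1), while regulatory T-like cells stood at 1.62 ± 0.710% and 1.57 ± 0.626% of all cells (exact p = 0.886). CD8 T-like cells were 1.64 ± 0.653% of all cells in untreated and 5.22 ± 2.90% in treated tumours (exact p = 0.0571, adjusted p = 0.326). T cells together were 9.62 ± 3.12% and 11.2 ± 5.31% (exact p = 0.629), and T cells without a named subset were 5.17 ± 1.99% and 2.82 ± 1.31%. Among the latter is a cluster led by Lef1, Tcf7 and S1pr1, genes of naive T cells, at 2.11 ± 1.39% and 0.32 ± 0.24% of cells (exact p = 0.0286, adjusted p = 0.337). Cd8a was seen in 37.4% and Cd4 in 21.0% of its cells. CD8 T cells in this cluster thus count among the T cells but not among the CD8 T-like cells. With subsets taken from single cells that hold coreceptor transcripts, the CD8 share of T cells was 23.2 ± 3.41% and 37.6 ± 11.1% and no longer passed the threshold (exact p = 0.114), and the log2 ratio differed by 0.97 (exact p = 0.114). These shares are of cells that passed the gradient, CD45 selection and capture.

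**Figure D1:**
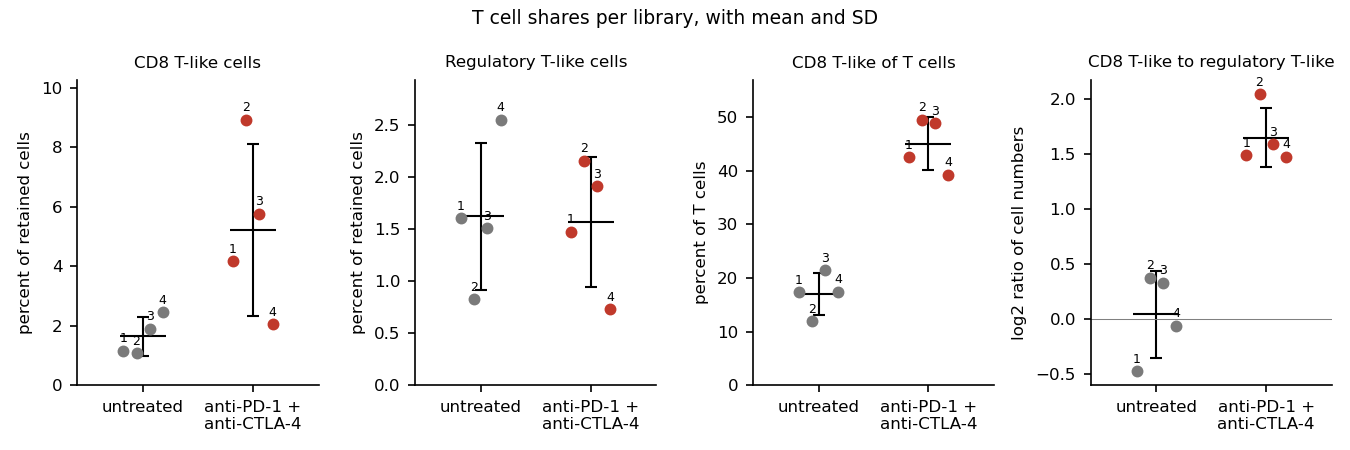
Shares of CD8 T-like and regulatory T-like cells and their ratio in each tumour; numbers are replicate labels, bars the mean and SD of 4 tumours.

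Conventional dendritic cells of type 1, the dendritic class that takes up and cross-presents antigen, formed a smaller share of cells in treated tumours. The cDC1-like share was 1.25 ± 0.160% in untreated and 0.690 ± 0.214% in treated tumours (exact p = 0.0286, adjusted p = 0.326), and this is the 1 class whose share passed the threshold, without an adjusted p under it. The largest classes did not pass: macrophage-like cells were 36.3 ± 6.85% and 28.4 ± 9.66% (exact p = 0.171), neutrophil-like cells 19.3 ± 3.19% and 26.1 ± 11.1% (exact p = 0.314), NK-like cells 5.25 ± 2.18% and 5.69 ± 2.95% (exact p = 0.8) and monocyte-like cells 2.67 ± 0.461% and 3.36 ± 1.88% (exact p = 0.6). B-like cells were 1.99 ± 1.72% and 0.576 ± 0.337%, CD4 conventional T-like cells 0.702 ± 0.235% and 1.28 ± 0.400%, and cDC2-like cells 2.38 ± 0.381% and 1.48 ± 0.715% (exact p = 0.0857 for each). Without any of the untreated replicates the cDC1-like share gave an exact p of 0.0571, and edgeR on cell numbers did not call it (log2 fold change −0.86). Treated 4, with the lower depth, also had the largest unnamed part.

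**Figure D2:**
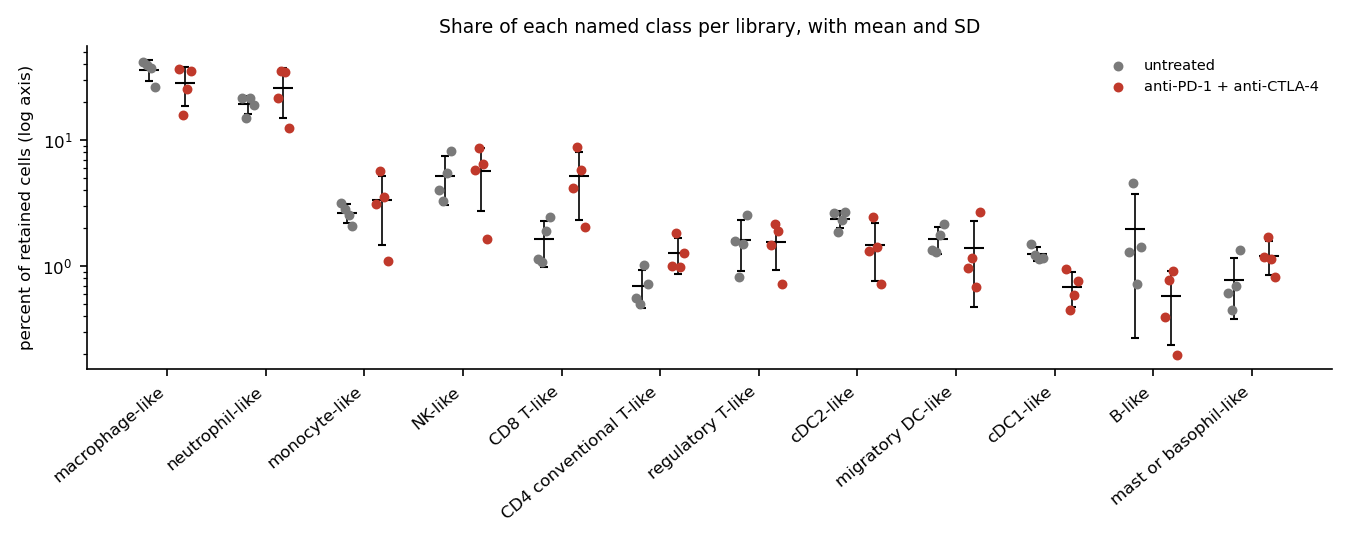
Percent of retained cells in each named class per tumour, on a log axis, with mean and SD of 4 untreated and 4 treated tumours.

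Of the classes fitted, neutrophil-like cells had the most called genes, with interferon-induced genes higher in treated tumours. Such counts also depend on power, which differed between classes in the simulated data. Of 6187 genes tested, 382 were higher and 125 lower. Gbp2, a guanylate-binding protein induced by interferon-γ, rose by a log2 fold change of 2.72 ± 0.22 (adjusted p = 1.0e-06, 341 ± 131 CPM in untreated and 2258 ± 207 CPM in treated tumours, n = 4 each, ENSMUSG00000028270, chromosome 3, 142620602–142638008, mm10). Of the 20 measured genes of the interferon-γ list, 19 rose and 0 fell (20 rose adjusted over the list alone), with a mean log2 fold change of 2.0. Examples are Gbp4 (3.74 ± 0.38), Gbp3 (3.04 ± 0.23), Gbp5 (2.51 ± 0.20) and the immunity-related GTPase Irgm1 (2.51 ± 0.20). The list has adjusted p = 0.189 with an estimated correlation. Of 24 type I interferon genes 22 rose (24 adjusted over the list alone), among them the antiviral Rsad2 (1.87 ± 0.14) and the transcription factor Stat2 (1.79 ± 0.14), with adjusted p = 0.257 with an estimated correlation. Of 17 genes for MHC class I presentation 16 rose (17 over the list alone, adjusted p = 0.236 with an estimated correlation), such as the proteasome activator Psme2 (1.62 ± 0.14) and Tapbpl (1.80 ± 0.16). All 4 treated tumours lay above all 4 untreated tumours for Gbp2. Of 10 monocyte markers Ifitm6, Ly6c2 and Plac8 rose (mean 0.23), and of 6 macrophage markers Cd68 rose and Adgre1 fell (mean −0.09).

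Chemokine genes rose in the same cells: 6 of 15 measured rose and 0 fell (7 over the list alone). Cxcl9 rose by 1.85 ± 0.35 and Cxcl10, both ligands of CXCR3, by 1.68 ± 0.21 (362 ± 96.6 and 1161 ± 296 CPM). The list has adjusted p = 0.417 with an estimated correlation. Cxcl9 is also a leading gene of a macrophage-like cluster. RNA from other cells was tested for interferon-γ genes only, so it is not excluded for Cxcl9 and Cxcl10. Of 20 glycolysis and hypoxia genes 9 rose (14 over the list alone), adjusted p = 0.431 with an estimated correlation. Gapdh rose by 0.90 ± 0.16 and Pkm by 0.65 ± 0.12. The list of classical macrophage activation had 3 of 6 rise (4 over the list alone, adjusted p = 0.271 with an estimated correlation), including Acod1 (0.80 ± 0.14), which makes itaconate. Genes of MHC class II presentation had 2 of 7 rise (4 over the list alone, adjusted p = 0.417 with an estimated correlation), with Ctss (0.93) and Cd74 (0.58 ± 0.13). RNA from other cells was not tested for Ctss and Cd74 either. Among the 125 lower genes were Ltc4s, the leukotriene C4 synthase, at −1.61 ± 0.33 (adjusted p = 0.0049, 77.2 ± 21.1 and 22.4 ± 16.2 CPM), Ptgs1 at −1.17 ± 0.22 and the thromboxane synthase Tbxas1 at −1.17 ± 0.21. Gss, the glutathione synthetase, stood at −1.23 ± 0.26. One of the 4 neutrophil-like clusters held 13.4 ± 1.47% of the class in untreated and 24.6 ± 6.95% in treated tumours. Without untreated 2 the count was 335.

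Of 5358 genes tested in monocyte-like cells 164 were higher and 57 lower, again with interferon-induced genes. The median UMI count of this class was 3991 to 4526 in untreated and 4754 to 6746 in treated tumours, and its effect was not tested. In the same animals 76 genes were higher in both monocyte-like and neutrophil-like cells. Of 10 neutrophil markers S100a8 and Slpi rose in monocyte-like cells (mean 0.45), so neutrophils within this class may add to the overlap. Of 20 interferon-γ genes 16 rose and 0 fell (19 over the list alone, mean 1.32, adjusted p = 0.189 with an estimated correlation). Gbp2 rose by 2.56 ± 0.22 (94.1 ± 56.0 and 549 ± 71.1 CPM) and Socs1, an inhibitor of cytokine signalling, by 2.1 ± 0.23. Cd274, which encodes the PD-1 ligand PD-L1, rose by 1.95 ± 0.19 (adjusted p = 9.3e-07, 33.6 ± 6.59 and 126 ± 10.2 CPM, ENSMUSG00000016496, chromosome 19, 29367455–29388095). Of 24 type I interferon genes 7 rose (10 over the list alone, adjusted p = 0.271 with an estimated correlation), with Isg15 at 0.95 and Herc6 at 0.89. Of 17 MHC class I genes 6 rose (9 over the list alone, adjusted p = 0.271 with an estimated correlation), with the peptide transporter Tap1 at 0.88 ± 0.12 and the proteasome subunit Psmb8 at 0.77 ± 0.13. In the classical activation list 4 of 9 rose (6 over the list alone, adjusted p = 0.236 with an estimated correlation), with Cxcl9 at 2.62 ± 0.48 and Acod1 at 2.35 ± 0.45. Of 17 glycolysis genes 1 rose (Gapdh 0.75 ± 0.12, adjusted p = 0.417 with an estimated correlation). Of 18 oxidative phosphorylation genes 2 rose (Cox7b 0.58 and Cox6c 0.51, adjusted p = 0.487 with an estimated correlation). Il1b differed by 0.09 (adjusted p = 0.70). Among the lower genes were Map3k1 (−0.85 ± 0.16), a kinase of stress signalling, Jmy (−1.09 ± 0.25), which nucleates actin, and Pim3 (−0.94 ± 0.21). The count of 221 was 104 without treated 2, 145 without untreated 2 and 116 with the stricter cell filter.

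In macrophage-like cells, summed over their clusters, no gene of 10284 passed the threshold with edgeR, where 1562 had a raw p under 0.05, and DESeq2 called 250. Within single clusters of the class edgeR did call genes, as given below. The largest fold changes among the genes fixed in the plan were Nos2, the inducible nitric oxide synthase, at 4.41 ± 0.61 (adjusted p = 0.055, 7.18 ± 4.20 and 150 ± 91.9 CPM, ENSMUSG00000020826, chromosome 11, 78920787–78960254), Cxcl9 at 2.59 ± 0.51 (adjusted p = 0.099) and Cd274 at 1.67 ± 0.31 (adjusted p = 0.099). Il6 stood at −0.92 ± 0.14 (adjusted p = 0.058) and Arg1 at 0.64 ± 0.29 (adjusted p = 0.34). Among the lists called higher with the preset correlation are the interferon-γ genes (23 measured, mean 1.13, 0 passed over all genes, 20 rose over the list alone, adjusted p = 0.271 with an estimated correlation), MHC class I genes (17, mean 0.76, 15 rose over the list alone, adjusted p = 0.271) and classical activation genes (11, mean 1.29, 8 rose over the list alone, adjusted p = 0.236, each with an estimated correlation). Proliferation genes were called lower with the preset correlation (34 measured, mean −0.68, 0 passed, adjusted p = 0.577 with an estimated correlation). Markers of neutrophils (13 genes, mean 0.83) and monocytes (12, mean 0.55) were also higher on average, with 0 passing, so such cells within the class are not excluded. The composition of the class differed between tumours: a cluster led by Cd163, Folr2 and Cbr2 held 40 ± 11.1% of the class in untreated and 23.9 ± 20.1% in treated tumours. A cluster led by Retnla, Ear2 and Lyz1 held 17.7 ± 4.0% and 9.27 ± 5.76%, and a cluster led by Cxcl9, Ass1, Ly6i and Arg1 held 9.83 ± 5.93% and 33.2 ± 27.4%. Within the cluster led by Cxcl9 and Ass1 edgeR called 343 higher and 225 lower genes of 6579. It called 72 and 32 in that led by Vcam1 and Pf4 and 28 and 1 in that led by Mmp12 and Spp1. It called 22 and 2 in that led by Retnla and Ear2 and 7 and 3 in that led by Cd163 and Folr2. These fits were chosen after the class result was seen and were not compared with other splits. The count of 0 became 5 without treated 1, 24 without treated 2 and 73 without treated 4, and splits of the tumours other than by treatment gave up to 1.

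CD8 T-like cells had 122 higher and 149 lower genes of 6432. Among the higher genes were Gzmb, the cytotoxic protease granzyme B, at 0.96 ± 0.14 (adjusted p = 0.00047, 520 ± 119 and 1016 ± 107 CPM, ENSMUSG00000015437, chromosome 14, 56258838–56262260), and the granzyme Gzmk at 1.31 ± 0.19. Also higher were the chemokine receptor Cxcr6 (0.95 ± 0.16), the interleukin-12 receptor subunit Il12rb2 (1.31 ± 0.23) and Ly6a (1.81 ± 0.20, adjusted p = 7.3e-05). Gzmb, Gzmk and Cxcr6 are among the markers used to name this class, and Gzmk leads a cluster that held 30.6 ± 7.90% of it in untreated and 47.4 ± 8.55% in treated tumours. Of 20 interferon-γ genes 5 rose and 0 fell (11 over the list alone, mean 0.53), with Igtp (1.34 ± 0.24), Gbp2 (1.30 ± 0.24) and Gbp7 (0.91 ± 0.15), and adjusted p = 0.236 with an estimated correlation. Of 5 monocyte markers Ly6c2 and Plac8 rose in this class (mean 0.63), so RNA or cells of monocytes are not excluded for part of these genes. Of 14 cytotoxic granule genes 3 rose (4 rose and 1 fell over the list alone, 8 with a fold change above 0, adjusted p = 0.271 with an estimated correlation). Of 13 genes of Th1 cells and interferon-γ production 3 rose (6 over the list alone, adjusted p = 0.271 with an estimated correlation). The type I interferon list (11 measured, mean 0.50, 0 passed, 3 rose over the list alone, adjusted p = 0.258 with an estimated correlation) was called, with Oas3 at 1.24 (adjusted p = 0.071) and Irf9 at 0.61 (adjusted p = 0.088). Pdcd1 differed by 0.50 ± 0.19 (adjusted p = 0.13), Ifng by 0.31 ± 0.26 (adjusted p = 0.57) and Ctla4 by −0.02 ± 0.14 (adjusted p = 0.98).

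Proliferation genes fell in the same CD8 T-like cells: 16 of 33 measured fell and 0 rose (29 fell over the list alone, mean −0.67, adjusted p = 0.337 with an estimated correlation). Stmn1, which destabilizes microtubules, fell by 0.91 ± 0.16 and Pcna, the clamp of DNA replication, by 0.78 ± 0.14, while Mki67 differed by −0.69 ± 0.22 (adjusted p = 0.079). The cycling cluster of the class, led by Mki67, Top2a and Cenpf, held 28.0 ± 9.58% of it in untreated and 12.3 ± 3.19% in treated tumours, and without this cluster the mean is 0.02 (adjusted p = 0.857). Of all cells it held 0.424 ± 0.0859% and 0.602 ± 0.275%, so its smaller part of the class goes with larger mean shares of the other CD8 T-like clusters. The cluster is mixed, with Cd8a in 58.2%, Ncr1 in 20% and Cd4 in 12.9% of its cells. Of 20 dissociation stress genes 5 fell (1 rose and 8 fell over the list alone, adjusted p = 0.527 with an estimated correlation), among them Fosb (−0.99 ± 0.17) and Dusp1 (−0.73 ± 0.13). Markers of NK cells fell as well, 6 of 10 tested (Klra7, Klrb1c, Klre1, Klri2, Ncr1 and Tyrobp). So did Klra1 (−3.01 ± 0.42), Vegfa (−2.50 ± 0.43), Spry2 (−2.24 ± 0.30), Fcer1g (−1.80 ± 0.31) and Klrb1b (−1.76 ± 0.26). Cells with a UMI of Ncr1 or Klrb1c made up 12.2 to 20.9% of the class in untreated and 2.59 to 8.23% in treated tumours. Without these cells 60 genes were higher and 40 lower of 5915. A smaller part of NK cells within the class may therefore add to the lower genes. With CD8 T cells taken by single-cell coreceptor transcripts, Vegfa, Fcer1g, Klrb1b, Stmn1 and Mki67 turn to higher values and the proliferation list is called higher (mean 0.26, adjusted p = 0.036). This gate also takes cells of unnamed clusters with T cell and myeloid markers, and their effect was not tested. With the stricter cell filter the mean of the proliferation list is 0.33 (adjusted p = 0.18). The count of 271 genes was 130 without treated 2, 168 without treated 3, 151 without untreated 2, 173 without untreated 3, 60 without the cycling cluster and 17 with the stricter cell filter.

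**Figure D3:**
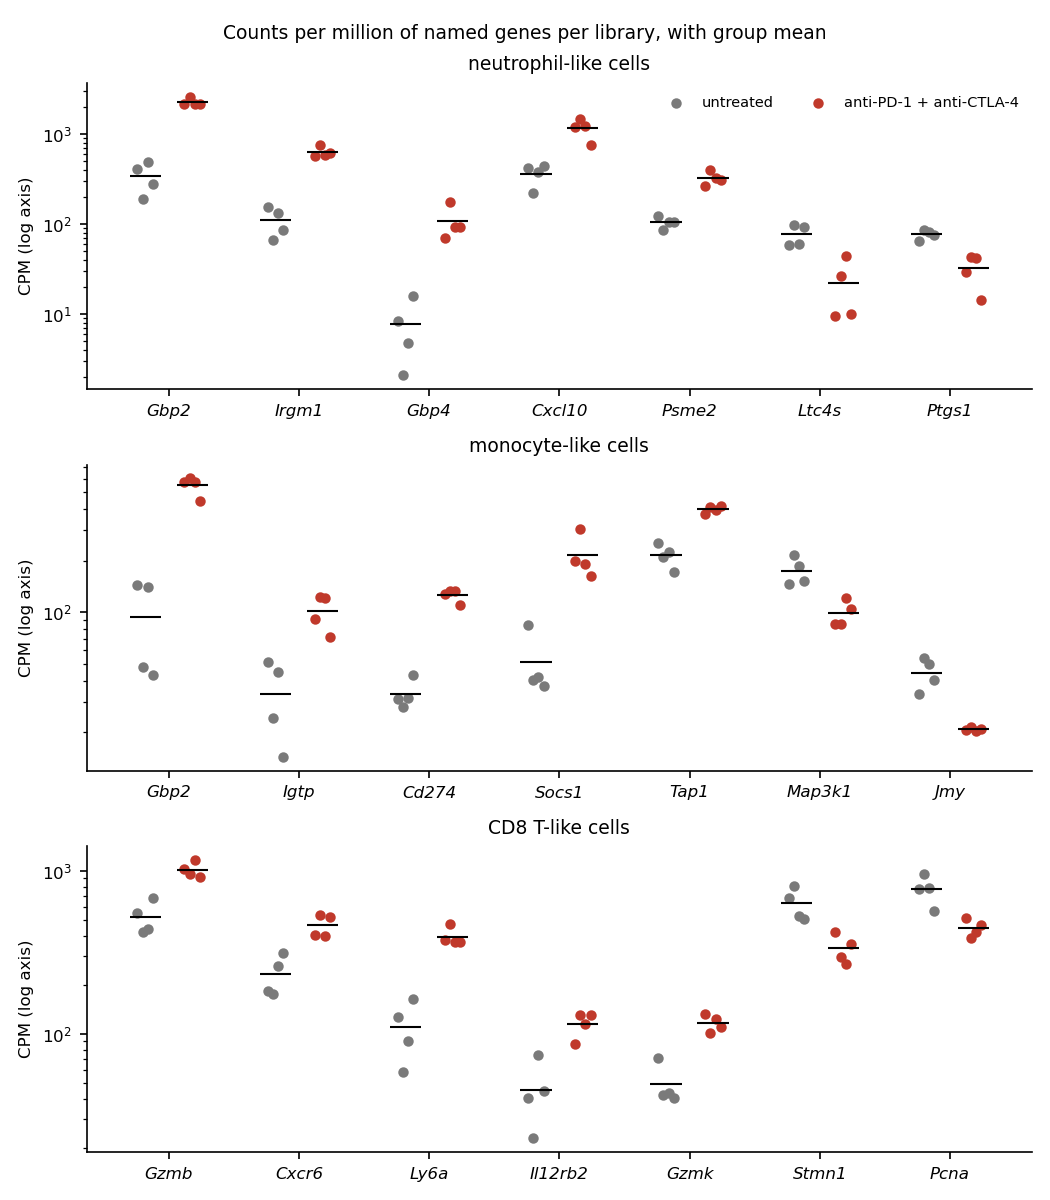
CPM within the class, on a log axis, of selected genes in neutrophil-like, monocyte-like and CD8 T-like cells. Points are tumours (4 untreated, grey, and 4 treated, red) and lines group means.

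NK-like cells had 25 higher and 5 lower genes of 6987, with granzymes higher in treated tumours. Gzmb rose by 0.94 ± 0.13 (587 ± 133 and 1135 ± 92.8 CPM) and Gzma by 0.77 ± 0.11 (3697 ± 525 and 6285 ± 531 CPM). Of 15 cytotoxic granule genes 3 rose (7 over the list alone, mean 0.71, adjusted p = 0.322 with an estimated correlation) and of 13 Th1 genes 2 rose (5 over the list alone, adjusted p = 0.189 with an estimated correlation), with Cxcr6 at 1.19 ± 0.24 and Il12rb2 at 0.70 ± 0.14. Il2ra, a subunit of the interleukin-2 receptor, was the 1 of 10 measured genes of the regulatory T effector list that rose (1.28 ± 0.26; 4 over the list alone, adjusted p = 0.189 with an estimated correlation). Of 19 interferon-γ genes 1 rose, Icam1 at 0.84 ± 0.18 (2 over the list alone, mean 0.34, adjusted p = 0.189 with an estimated correlation). Markers of T cells also had means above 0 in this class, with 0 passing: 0.82 for CD8 T cells (6 genes), 0.61 for CD4 conventional T cells (5), 0.64 for regulatory T cells (4) and 0.48 for gamma-delta T cells (4). Since T cells express Cxcr6 and Il2ra too, T cells within the class are not excluded for these genes. Ly6a rose by 1.96 ± 0.30, and Spry2, an inhibitor of receptor kinase signalling, fell by 0.71 ± 0.13. CD8 T-like and NK-like cells had 17 higher genes in common. A cluster led by Klra4, Klra8 and Eomes held 69.9 ± 4.71% of NK-like cells in untreated and 45.9 ± 3.07% in treated tumours, and clusters led by Gzmc and Xcl1 (17.6 ± 6.08% and 30.7 ± 1.96%) and by Gzma and Prf1 (12.5 ± 2.43% and 23.4 ± 3.20%) held the rest. Within these clusters, in the same order, the cytotoxic granule list had means of 0.36, 0.42 and 0.40 (12, 15 and 10 genes), against 0.71 in the class. Part of the class mean may therefore come from the shift among clusters. The cluster led by Gzmc and Xcl1 stayed unnamed with the larger pseudocount. The count of 30 was 9 with the stricter cell filter and 57 with DESeq2.

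In regulatory T-like cells some effector genes were lower in treated tumours. Of 4205 genes 36 were higher and 50 lower, and of 17 regulatory T effector genes 5 fell and 0 rose (1 rose and 8 fell over the list alone, mean −0.35, adjusted p = 0.271 with an estimated correlation). The growth factor Areg fell by 1.07 ± 0.17 (adjusted p = 0.00068, 1497 ± 162 and 715 ± 250 CPM), the suppressive cytokine Il10 by 1.02 ± 0.27 (adjusted p = 0.042), Klrg1 by 0.88 ± 0.17, and Ctla4, which encodes a target of the treatment, by 0.55 ± 0.15 (adjusted p = 0.042, 2689 ± 787 and 1822 ± 111 CPM). Of 15 T cell activation genes 3 fell (1 rose and 6 fell over the list alone, adjusted p = 0.271 with an estimated correlation), among them Nr4a1 (−0.76 ± 0.14), induced by antigen receptor signalling, and Tnfrsf9 (−0.53 ± 0.13). Cxcr3 rose by 1.21 ± 0.24 and Sla2 by 1.34 ± 0.35, and the metallothionein Mt2 fell by 2.29 ± 0.35. Trbc2 rose, but it is on the marker lists of both CD8 T and CD4 conventional T cells, so it points to neither. The 4 markers tested of each list had means of 1.04 and 0.43. For NK cells 3 markers had a mean of 0.71 with 0 passing. Of 4 monocyte markers Ly6c2 rose and Ccr2 fell (mean 0.75). Other cells within the class are not excluded as a source of the higher genes or a dilution of the lower ones. The median UMI count of the class was 2645 to 2836 in untreated and 3819.5 to 4871 in treated tumours, and its effect was not tested. Foxp3, the lineage factor, differed by −0.07 ± 0.15 (adjusted p = 0.88), and the interferon-γ list was not called (20 measured, 0 passed, mean 0.07, adjusted p = 0.659). The list was called higher with the single-cell gate (mean 0.26, adjusted p = 0.00014). That gate covers all retained cells, so it also takes cells of unnamed clusters with T cell and myeloid markers. In 1 of these, with Cxcl9 among its leading genes, Foxp3 was seen in 29.9% and Lyz2 in 86.1% of cells. RNA or cells of the myeloid lineage are therefore not excluded for this call. The count of 86 was 30 without treated 2, 44 without untreated 1 and 30 without untreated 3. With a replicate left out, Ctla4 lost its call in 6 fits (−0.66 to −0.35) and Il10 in 6 (−1.43 to −0.81). Tnfrsf9 lost it in 4 (−0.61 to −0.42) and Sla2 in 5 (1.16 to 1.54), so these calls depend on single tumours. In CD4 conventional T-like cells 2 genes were higher, Ifitm1 (1.77 ± 0.30) and the granzyme inhibitor Serpinb9 (1.18 ± 0.21), and 1 lower, the chemokine receptor Cxcr4 (−1.30 ± 0.21), of 2834. Other splits of the tumours gave up to 10.

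Interferon-induced genes were also higher in cDC2-like cells, where 31 genes were higher and 4 lower of 5797. Of 20 interferon-γ genes 8 rose (14 rose and 1 fell over the list alone, mean 0.88, adjusted p = 0.271 with an estimated correlation), with Iigp1 (2.67 ± 0.41) and Ifi47 (1.30). Of 17 type I interferon genes 4 rose (8 over the list alone, adjusted p = 0.288 with an estimated correlation), with Isg15 (1.62 ± 0.25). Of 17 MHC class I genes 3 rose (11 over the list alone, adjusted p = 0.236 with an estimated correlation). Areg (−1.55 ± 0.33) and the lipid synthesis enzyme Acly (−0.84 ± 0.17) fell. In migratory DC-like cells 7 genes were higher and 1 lower of 3973. The interferon-γ list was called there with 0 of 14 genes passing (6 rose over the list alone, mean 0.43, adjusted p = 0.236 with an estimated correlation), and so was the type I list with 0 of 9 passing (3 rose over the list alone, adjusted p = 0.337 with an estimated correlation). Higher were Cxcl9 (3.75 ± 0.60), Acod1 (3.54 ± 0.55), the inflammasome sensor Nlrp3 (2.37 ± 0.43) and Cebpb (2.11 ± 0.36), and lower Idi1 of cholesterol synthesis (−1.50 ± 0.26). Markers of other myeloid classes moved with them: of 5 neutrophil markers Hdc rose (mean 2.03), and of 3 monocyte markers Plac8 rose (mean 1.22). Acod1 is itself among the markers used for neutrophils. Neutrophils or monocytes within the class are therefore not excluded. In cDC1-like cells the 2 genes called of 4618 were higher, Upp1 (3.96 ± 0.62) and the prostaglandin synthase Ptgs2 (2.91 ± 0.44). Upp1 is also a leading gene of a neutrophil-like cluster, and the 4 neutrophil markers tested in cDC1-like cells had a mean of 1.25 with 0 passing, so neutrophils within this class are not excluded either. Its interferon-γ list was called with 0 of 12 genes passing (5 rose over the list alone, mean 0.58, adjusted p = 0.271 with an estimated correlation), and its type I list was not called (7 measured, 0 passed, adjusted p = 0.458). In treated 4 the median UMI count was 994 in migratory DC-like cells (5089 to 5275 in the other treated tumours) and 1178 in cDC1-like cells (6915 to 9701.5). In mast or basophil-like cells, with 3 untreated and 4 treated tumours, 2 of 1883 were higher, among them the basophil protease Mcpt8 (1.28 ± 0.21). Of 4 monocyte markers Ly6c2 rose in these cells (mean 0.99), so RNA or cells of monocytes are not excluded there. The class joins a basophil-like cluster, led by Mcpt8, with a mast cell-like cluster, and the former held 75.3 ± 4.77% of it in untreated and 85.4 ± 1.37% in treated tumours (exact p = 0.0286), so part of the change may come from this shift. The cDC2-like count of 35 was 9, 11, 13 and 132 without treated 1, 2, 3 and 4 and 6, 14 and 12 without untreated 1, 2 and 3, and 45 genes were called in another split. The migratory DC-like count of 8 was 14, 5 and 15 without treated 2, 3 and 4 and 19 and 5 without untreated 1 and 3, and 0 with the stricter cell filter.

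Whole libraries, which read composition and expression together, had 40 higher and 4 lower genes of 13072. Nos2 rose by 4.06 ± 0.50 (adjusted p = 0.024), Ly6i by 3.21 ± 0.26 (adjusted p = 0.010, 9.32 ± 1.06 and 86.2 ± 31.1 CPM), Gzmk by 2.60 ± 0.31, Gbp2 by 2.48 ± 0.33 and Cxcl9 by 1.96 ± 0.30, and Ltc4s fell by 1.13 ± 0.17 (adjusted p = 0.042). Of 26 interferon-γ genes 7 rose (25 rose and 1 fell over the list alone, mean 1.19, adjusted p = 0.236 with an estimated correlation). Of 17 cytotoxic granule genes 1 rose (10 over the list alone, mean 1.22, adjusted p = 0.337 with an estimated correlation). DESeq2 called 544 genes. The edgeR count of 44 was 22, 3 and 106 without treated 2, 3 and 4 and 3, 3, 5 and 8 without untreated 1, 2, 3 and 4.

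Over all classes, camera with the preset correlation called 79 of 235 list tests, 61 higher and 18 lower. None of the 79 holds with an estimated correlation (adjusted p at least 0.189), and fry, which tests whether a list moves on balance in 1 direction, called 32. The interferon-γ list was called in 9 of the 11 fits in which it was tested, the type I interferon list in 7 of 10, the MHC class I list in 7 of 12 and the glycolysis list in 9 of 12. The MHC class II list was called in opposite directions, with 0 genes passing outside neutrophil-like cells. It was higher in neutrophil-like and macrophage-like cells (10 measured in the latter, mean 0.27, adjusted p = 0.576 with an estimated correlation). It was lower in migratory DC-like cells (9 measured, mean −0.50, 1 fell over the list alone, adjusted p = 0.511 with an estimated correlation) and whole libraries (10 measured, mean −0.47, 3 fell over the list alone, adjusted p = 0.521 with an estimated correlation). Cholesterol synthesis was called lower in 4 of 10, with 0 of 9 genes passing in cDC1-like cells (4 fell over the list alone, mean −0.60, adjusted p = 0.236 with an estimated correlation) and 1 of 9 falling in migratory DC-like cells (adjusted p = 0.346 with an estimated correlation).

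**Figure D4:**
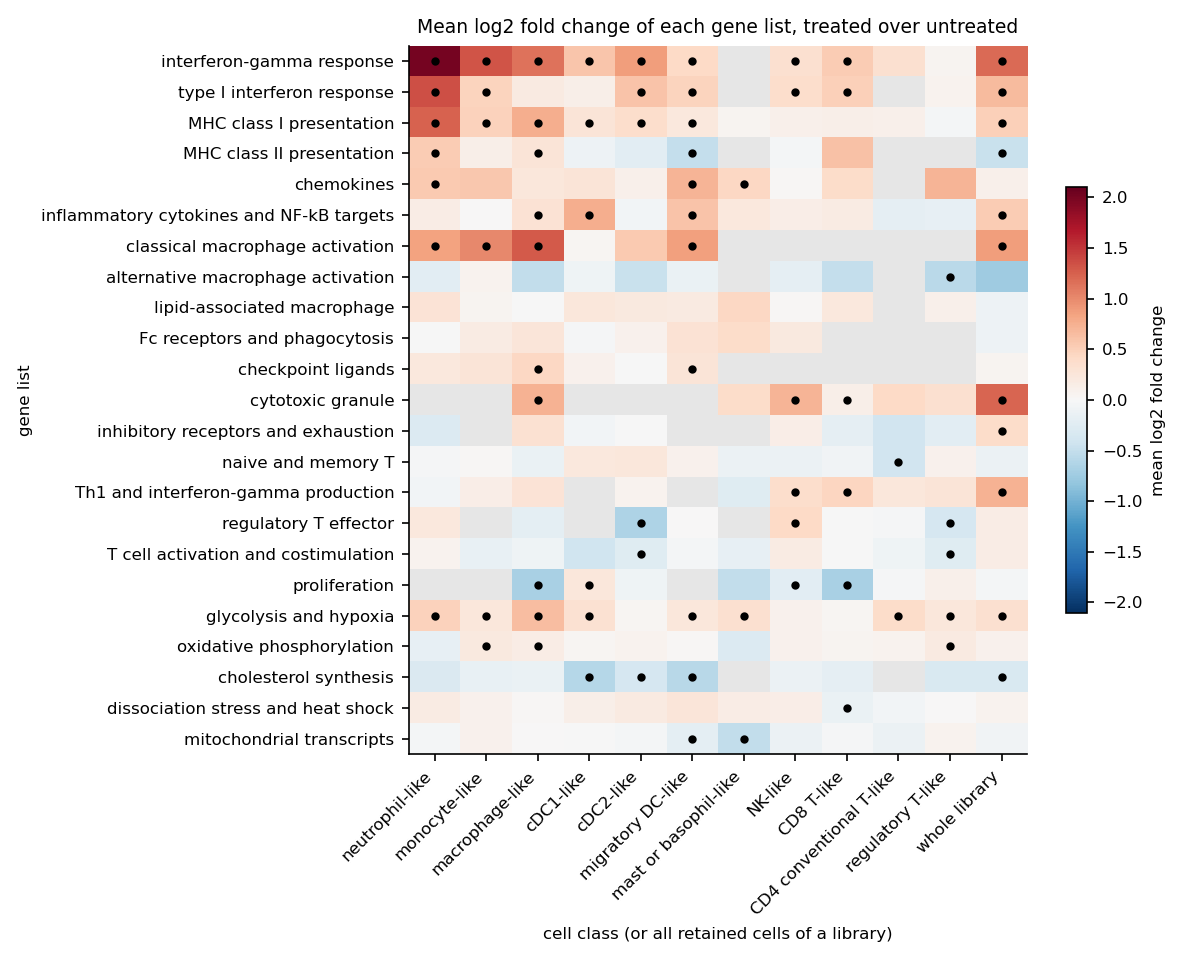
Mean log2 fold change of each gene list in each cell class, treated over untreated (4 tumours each, 3 untreated for mast or basophil-like cells); dots mark lists called by camera with the preset correlation.

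The responses differed between classes within the same animals. The interferon-γ list stood at −0.16 ± 0.23 in macrophage-like minus CD8 T-like cells of untreated and at 0.45 ± 0.35 of treated tumours, so that it rose by 0.61 more in macrophage-like cells (exact p = 0.0286, adjusted p = 0.0381). It did not differ in this way between macrophage-like and monocyte-like cells (−0.19, exact p = 0.4). Within macrophage-like clusters the list rose by 0.49 in that led by Cd163 and Folr2 and by 0.79 to 1.39 in the others fitted. In CD8 T-like cells it rose by 0.53. A shift among macrophage-like clusters may therefore add to the difference. Proliferation genes in CD8 T-like minus CD4 conventional T-like cells went from −1.23 ± 0.39 to −1.87 ± 0.27 (a difference of −0.64, exact p = 0.0286, adjusted p = 0.0381). In CD8 T-like minus regulatory T-like cells they went from 0.15 ± 0.34 to −0.63 ± 0.35 (−0.78, exact p = 0.0286, adjusted p = 0.0381). These are means over 33 proliferation genes in CD8 T-like cells against 5 and 14 in the other classes, and over 23 and 20 interferon-γ genes. Over the genes tested in both classes the differences are −0.55 and −0.74 for proliferation and 0.63 for interferon-γ (exact p = 0.0286 each), a setting added after the data were seen. The proliferation differences are 0.05 and −0.08 without the cycling cluster and 0.37 and 0.36 with the stricter cell filter. With the single-cell gate they are −0.17 (exact p = 0.657) and −0.41 (exact p = 0.343), and with doublets kept the one to CD4 conventional T-like cells is −0.26 (exact p = 0.286). The interferon-γ difference lost the call without untreated 4 (0.50, exact p = 0.0857), with the stricter filter (exact p = 0.0571) and with the single-cell gate (exact p = 0.114). The proliferation differences lost it without untreated 2, treated 2, treated 3 or treated 4, and the one to regulatory T-like cells also without treated 1 (exact p = 0.0571 each). Groups of 3 and 4 that lie fully apart can also give this p, so overlap is not implied.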

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

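Libraries far from the other 3 of their group were set apart by the gap to the nearest value over the whole range of the group (Dixon's ratio, above its 95% critical value). This was applied to 565 groups of 4, and 34 were set apart where 28.25 would be expected by chance. Of the 34, 9 lie in treated 4. The ratio follows each item listed. The predictions for RNA from other cells, NK cells within the class and naive T cells were written before their tests were run. Those for cluster shifts, cycling cells, cluster names and other splits of the tumours were written after the result had been seen.

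Treated 4 had the lowest median UMI count per cell (0.924, at 1377 against 2786 to 2902) and the lowest median gene number (0.885, at 752 against 1213 to 1273). It also had the highest endothelial-like share (0.900, at 0.962% against 0.0392 to 0.132%) and tumour epithelial-like share (0.843, at 0.812% against 0.132 to 0.239%). Untreated 4 had the highest gamma-delta T-like share (0.856, at 1.03% against 0.249 to 0.362%) and treated 1 the highest plasma-like share (0.842, at 0.421% against 0.0588 to 0.116%).

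Among genes, in log2 CPM, CD8 T-like cells had Gzmk high in untreated 1 (0.868, at 6.20 against 5.43 to 5.53) and Ly6a high in treated 2 (0.900, at 8.88 against 8.52 to 8.56). Spry2 was high in treated 1 (0.851, at 5.45 against 4.06 to 4.27). Pdcd1 was low in CD4 conventional T-like cells of treated 4 (0.836, at 8.08 against 8.91 to 9.07), and Gzmb was low in regulatory T-like cells of untreated 4 (0.837, at 10.65 against 11.10 to 11.19). NK-like cells of treated 4 had Elmsan1 low (0.850, at 6.92 against 7.16 to 7.20) and Ly6a high (0.855, at 7.70 against 6.64 to 6.79). In cDC2-like cells Idi1 was high in untreated 1 (0.949, at 7.65 against 6.43 to 6.50) and Tap1 in treated 2 (0.904, at 8.89 against 8.38 to 8.43). Migratory DC-like cells had Erap1 high in treated 1 (0.888, at 6.72 against 6.05 to 6.13). H2-DMb2 was low in untreated 4 (0.944, at 5.73 against 6.97 to 7.04) and mt-Nd5 high in untreated 1 (0.880, at 8.51 against 8.35 to 8.37).

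In macrophage-like cells untreated 3 had Ctss high (0.835, at 11.54 against 11.29 to 11.33) and H2-Q7 low (0.836, at 6.24 against 6.47 to 6.51). Its Pdcd1lg2 was high (0.961, at 6.72 against 5.79 to 5.83). Il6 was low in treated 3 (0.927, at 5.16 against 5.70 to 5.74). Monocyte-like cells had Gapdh high in untreated 4 (0.878, at 8.67 against 8.23 to 8.28) and Gbp2 low in treated 4 (0.833, at 8.81 against 9.17 to 9.24). Herc6 was high in treated 1 (0.836, at 6.12 against 5.85 to 5.89), Prkd3 high in treated 4 (0.843, at 5.85 against 5.39 to 5.47) and Socs1 high in untreated 1 (0.852, at 6.46 against 5.35 to 5.52). Neutrophil-like cells had Clic5 low in untreated 1 (0.868, at 0.20 against 2.12 to 2.42) and Eprs low in untreated 2 (0.838, at 6.18 against 6.48 to 6.54). Gbp2 was high in treated 2 (0.917, at 11.33 against 11.06 to 11.08). In whole libraries of treated 1 Gbp6 was high (0.863, at 5.20 against 4.94 to 4.97) and Nos2 low (0.857, at 4.02 against 5.64 to 5.91). Pkm was low in untreated 2 (0.849, at 8.44 against 8.79 to 8.86).

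List differences between classes of the same animals that changed with treatment were −0.64 (proliferation, CD8 T-like minus CD4 conventional T-like), −0.78 (proliferation, CD8 T-like minus regulatory T-like) and 0.61 (interferon-γ, macrophage-like minus CD8 T-like).

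The higher interferon-γ genes in neutrophil-like cells could come from RNA released by other cells. The median of the called list genes stood at 174 to 266% of the whole-library level in treated libraries, and the median of genes of macrophages and lymphocytes at 2.2 to 3.3%. The ratio of these medians was at least 59.5, which excludes this source for the list as a whole. Single genes lie outside these ranges: Gbp8, Psmb10 and Wars at 34.9 to 77.2% and Iigp1 at 7.46 to 16.6%, with Apoe of the other cells at 4.35 to 14.7%. For Iigp1 this source is not excluded. Genes outside the list, such as Cxcl9, Cxcl10 and Cd74, were not tested in this way. A shift among neutrophil-like clusters is excluded too, since the list rose by at least 1.41 within each of the 4 clusters. A change within these cells stays open, and its source was not tested. Type I interferon genes rose as well (22 of 24), and Ifng in CD8 T-like cells differed by 0.31 (adjusted p = 0.57).

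The lower proliferation genes in CD8 T-like cells could come from a smaller share of the cycling cluster in the class. Without it the mean log2 fold change is 0.0244, but this cluster is set apart by the same kind of genes, so the test cannot tell. Of all cells the cycling cluster was not lower (0.424% in untreated and 0.602% in treated tumours, exact p = 0.286), while the other CD8 T-like clusters went from 0.708 to 2.29% (exact p = 0.0857) and from 0.510 to 2.33% (exact p = 0.0286). NK cells within the class were tested by leaving out each cell with a UMI of Ncr1 or Klrb1c. The mean was then −0.316 against −0.67 before, less than the amount set for excluding this cause, so the test cannot tell, and 60 genes were higher and 40 lower of 5915. A UMI filter also takes CD8 T cells that express these receptors.

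The higher CD8 T-like part of T cells could reflect the names given to clusters. Taken from single cells within the T cell clusters, the CD8 share still differed by 17.9 points (exact p = 0.0286, adjusted p = 0.0857), so the names of these clusters alone do not give it. They may add to it, since the difference by names is 28.1 points. The log2 ratio to regulatory T cells differed by 0.69 within these clusters (exact p = 0.143). The planned gate over all cells gave 14.4 points (exact p = 0.114), and neither passed. Fewer cells of the naive-like cluster alone do not give the difference by names: without that cluster it was 24.7 points (21.7 ± 2.08% and 46.4 ± 5.71%). Another cluster with Tcf7 among its leading genes, at 1.97 ± 0.56% and 1.37 ± 0.76% of cells, stayed among the T cells. Fewer naive T cells outside the 1 cluster left out are therefore not excluded. A loss of other T cells and a gain of CD8 T cells could both lead to a higher CD8 share. They cannot be told apart without cell numbers per tumour.

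Counts of called genes were compared with the 35 splits of the tumours into groups, the real one included. As many genes as by treatment were called in 1 split for neutrophil-like (507 genes, at most 0 in another split), CD8 T-like (271, 2), monocyte-like (221, 2), regulatory T-like (86, 2), NK-like (30, 3) and migratory DC-like cells (8, 3) and whole libraries (44, 0). For CD4 conventional T-like (3 genes) and mast or basophil-like cells (2) 3 splits gave as many and for cDC1-like (2) and cDC2-like cells (35) 2 splits. The counts of these latter classes are not told apart from other splits. For macrophage-like cells the count of 0 decides nothing here, since no split can give fewer. Camera called 79 lists by treatment and up to 67 in another split. In the 18 splits with 2 treated tumours on each side it called 1 to 45 lists, so the preset correlation also calls lists where treatment is balanced. Fry called 32 by treatment and at most 2 in another split.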

How the results depend on the processing

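Of 1991 comparisons of named genes with other settings, 1706 kept direction and side of the threshold, 101 gained and 154 lost the call and 30 reversed. Of 1999 with a replicate left out these were 1747, 37, 200 and 15. For called lists 544 of 724 were kept and 175 lost, mostly with an estimated correlation or fry. The CD8 T-like part of T cells (26.3 to 30 points), the log2 ratio of CD8 T-like to regulatory T-like cells (1.43 to 1.71), the interferon-γ list in neutrophil-like cells (1.90 to 2.11), the number of called lists (75 to 87) and the NK-like gene count (22 to 38) held without any replicate. Where not stated otherwise the cause of a change was not tested. Settings added after the data were seen are cycling clusters left out, unnamed clusters left out, the gate within T cell clusters, the gate for expression, list differences over genes tested in both classes and the other naming rules. Exact tests without a replicate use 35 assignments, with 0.0286 as the smallest p. Classes with few cells could not be fitted with at least 50 cells, nor mast or basophil-like cells with the stricter filter or without untreated 1, 3 or 4. Depth limits small classes and treated 4. Clusters under the stricter filter were not identical when the steps were run in another computing environment, while those of the other settings were, so values of that setting are approximate.

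Classes past the share threshold numbered 2 without unnamed clusters, 2 with the stricter filter and 3 with edgeR on cell numbers (0 to 3 without a replicate). The CD8 T-like share differed by 4.14 without unnamed clusters, 3.23 with the stricter filter and 1.67 in log2 with edgeR on cell numbers (2.34 to 4.64 without a replicate; 4.64 without treated 4, exact p = 0.0286). The 3 with edgeR are CD8 T-like, B-like and endothelial-like. The cDC1-like share lost its call with edgeR, at −0.86 in log2, and ranged from −0.650 to −0.485 points without a replicate. Reversals were CD4 conventional T-like −1.22 without the coreceptor rule, ILC2-like −0.0645, NK-like −0.533 and monocyte-like −1.95 with the stricter filter, NK-like −0.320 with doublets kept and −0.354 with the larger pseudocount, and plasma-like 0.00700 at resolution 2. Without a replicate, shares ranged for ILC2-like from −0.0209 to 0.0516, NK-like −0.566 to 1.79, fibroblast-like −0.159 to 0.0566, monocyte-like −0.0819 to 1.45, plasma-like −0.108 to 0.0927, regulatory T-like −0.318 to 0.257, tumour epithelial-like −0.0246 to 0.219, T cells of all −0.718 to 3.55 and macrophage-like of macrophage-like plus monocyte-like −8.52 to −0.768. With the single-cell gate the CD8 part of T cells differed by 14.4 and the log2 ratio by 0.97 (0.69 within T cell clusters). Regulatory of CD4 T cells reversed to 3.56 by the gate within T cell clusters and 10.3 without the coreceptor rule.

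Gene counts without a gene filter were 60 (CD4 conventional T-like), 567 (CD8 T-like), 49 (cDC1-like), 193 (cDC2-like), 103 (macrophage-like), 73 (mast or basophil-like), 107 (migratory DC-like), 154 (NK-like), 165 (regulatory T-like) and 99 (whole libraries). DESeq2 gave 19 (CD4 conventional T-like), 250 (macrophage-like), 21 (mast or basophil-like), 20 (migratory DC-like), 57 (NK-like) and 544 (whole libraries). With doublets kept they were 5 (CD4 conventional T-like), 1 (cDC1-like), 15 (macrophage-like), 1 (mast or basophil-like) and 15 (migratory DC-like). With the stricter filter they were 25 (CD4 conventional T-like), 17 (CD8 T-like), 4 (macrophage-like), 0 (migratory DC-like), 116 (monocyte-like) and 9 (NK-like). At resolution 2 they were 111 (CD8 T-like), 21 (cDC2-like), 4 (macrophage-like) and 1 (mast or basophil-like). Without cycling clusters they were 60 (CD8 T-like) and 13 (macrophage-like), with RLE factors 3 (macrophage-like), with at least 50 cells 51 (regulatory T-like) and with the gate 7 (CD4 conventional T-like). Without a replicate they ranged from 3 to 10 (CD4 conventional T-like), 130 to 323 (CD8 T-like), 0 to 3 (cDC1-like), 6 to 132 (cDC2-like), 0 to 73 (macrophage-like), 0 to 9 (mast or basophil-like), 5 to 19 (migratory DC-like), 104 to 188 (monocyte-like), 335 to 545 (neutrophil-like), 30 to 102 (regulatory T-like) and 3 to 106 (whole libraries).

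The proliferation list in CD8 T-like cells was 0.33 with the stricter filter (adjusted p = 0.18), 0.26 with the gate (called higher, adjusted p = 0.036) and 0.0244 without the cycling cluster. With an estimated correlation 0 lists were called, so the call was lost for interferon-γ at means of 0.53 (CD8 T-like), 0.58 (cDC1-like), 0.88 (cDC2-like), 1.13 (macrophage-like), 0.43 (migratory DC-like), 1.32 (monocyte-like), 2.0 (neutrophil-like), 0.34 (NK-like) and 1.19 (whole libraries) and for proliferation in CD8 T-like cells at −0.67. Fry called 32 lists and not proliferation in CD8 T-like cells (−0.67) or interferon-γ in cDC1-like (0.58) and cDC2-like cells (0.88). With the gate, which also takes cells of unnamed clusters with myeloid markers, interferon-γ was called in CD4 conventional T-like (0.59) and regulatory T-like cells (0.26). Without a replicate it ranged from 0.31 to 0.57 and from −0.0134 to 0.15. The difference in interferon-γ between macrophage-like and CD8 T-like cells was 0.679 with the stricter filter and 0.33 with the gate (0.44 to 0.69 without a replicate), and that between macrophage-like and monocyte-like cells 0.0893 with doublets kept. For proliferation, CD8 T-like minus CD4 conventional T-like was −0.26 with doublets kept, 0.37 with the stricter filter, −0.17 with the gate and 0.0540 without the cycling cluster (−0.75 to −0.45 without a replicate), and CD8 T-like minus regulatory T-like 0.36, −0.41 and −0.0831 for the last 3 of these (−0.93 to −0.62).

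Genes that reversed in CD4 conventional T-like cells were Ctla4 (0.0433 without a gene filter, 0.33 with the gate), Gzmb (0.34 with DESeq2, 0.0687 without a gene filter, 0.29 with the gate), Pdcd1 (0.0429 without a gene filter, 0.92 with the gate) and Pfkp (−0.10 with the gate). In CD8 T-like cells they were Ctla4 (0.0373 without a gene filter, 0.29 with the gate), Fcer1g (0.42 with the stricter filter, 0.16 with the gate), Ifng (−0.19 with the stricter filter, −0.0035 without the cycling cluster), Klrb1b (0.32 with the gate), Mki67 (0.15 and 0.74 with the stricter filter and the gate), Pdcd1 (−0.0164 with the stricter filter, −0.14 without the cycling cluster), Stmn1 (0.12 with the stricter filter, 0.35 with the gate, 0.22 without the cycling cluster) and Vegfa (0.19 with the gate). Il1b in monocyte-like cells was −0.01 with doublets kept and −0.15 with the stricter filter, and in regulatory T-like cells the gate gave Foxp3 0.0738, Gzmb 0.16 and Mki67 0.94. Without a replicate the ranges were −0.28 to 0.0851 for Ctla4, −0.37 to 1.30 for Gzmb and −0.28 to 0.12 for Pdcd1 in CD4 conventional T-like cells, −0.10 to 0.14 for Ctla4 and −0.0047 to 0.54 for Ifng in CD8 T-like cells, −0.00040 to 0.19 for Il1b in monocyte-like cells and −0.15 to 0.0444 for Foxp3 in regulatory T-like cells.

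With the replicate number as a block, classes past the share threshold numbered 2, CD8 T-like (1.11 in logits) and B-like. The cDC1-like share lost its call (−0.63 in logits), and ILC2-like (−0.0714), NK-like (−0.0124) and plasma-like shares (0.400) reversed. Gene counts in the paired fit were 9 (CD4 conventional T-like), 160 (CD8 T-like), 1 (cDC1-like), 15 (cDC2-like), 9 (mast or basophil-like), 17 (migratory DC-like), 55 (NK-like) and 0 (whole libraries); Gzmb in CD4 conventional T-like cells was 0.32 and Ctla4 in CD8 T-like cells 0.0141. The labels do not say that replicate numbers pair the tumours. Across 13072 genes the correlation of libraries with the same number, after the group means were taken off, was 0.41, −0.053, 0.14 and −0.36. Only number 1 correlated best with its own, which gives little sign of pairing but cannot exclude a shared batch. Whether a call lost under this block is a weakness stays open.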

Other observations

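A cluster without a name, led by the C-type lectin genes Cd209g, Cd209f, Cd209b and Cd209d and by Fcna and Lyve1, held 791 cells, at 4.20 ± 3.0% of untreated and 0.921 ± 1.21% of treated cells (exact p = 0.0857, adjusted p = 0.337). It scored best on the macrophage list and stayed unnamed since its leading genes hold more markers of another class. A cluster of 73 cells led by the granzymes Gzmg, Gzme, Gzmd and Gzmf was at 0.0776 ± 0.0697% and 0.341 ± 0.18% (exact p = 0.0286, adjusted p = 0.337), and a related cluster of 67 cells led by Gzmf, Gzmd and Gzmg came from treated 4 alone. Neither was used in any class.

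Some genes were higher in several classes of the same animals: 25 in cDC2-like and monocyte-like cells, 24 in CD8 T-like and monocyte-like cells and 21 in CD8 T-like and neutrophil-like cells. The classes come from the same libraries, and the overlap this alone would give was not computed. In macrophage-like cells the checkpoint ligand list was called higher (11 measured, 0 passed, 5 rose when adjusted over the list alone, mean 0.44, adjusted p = 0.527 with an estimated correlation), with Pdcd1lg2 at 1.13 (adjusted p = 0.12). In CD4 conventional T-like cells the naive and memory list was called lower (11 measured, 0 passed, 3 fell when adjusted over the list alone, mean −0.40, adjusted p = 0.271 with an estimated correlation). Lists of lipid-associated macrophages and of Fc receptors and phagocytosis had no call in any class. Within macrophage-like clusters the interferon-γ list had a mean of 0.49 in the cluster led by Cd163 and Folr2 and 1.39 in that led by Mmp12 and Spp1. It was 1.28 in that led by Cxcl9 and Arg1. In those led by Retnla and Ear2 and by Vcam1 and Pf4 it was 0.79 and 1.10. This look within clusters was chosen after the class result was seen.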
